A study of Mus musculus with 50 samples.

How the data were processed

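The deposited files were used: a table of integer counts, a table of CPM (count over library total, on the usual scale) and a table of log2 values, each with 50 library columns, and per the file headers the columns name the model, Cre status, age and animal. Per the submitters' processing notes, reads were processed with CASAVA 1.8.2, aligned with STAR 2.5.2b to GRCm38, counted with featureCounts 1.5.1 of Subread and transformed with limma 3.28.21. The annotation release used for counting is not given in the sources used here. Per the labels, total RNA of sorted microglia (1 ng) was amplified with the SMARTer Ultra Low Input kit version 4 (11 cycles) and tagmented with Nextera XT from 150 pg cDNA. The deposited CPM table was checked against the count table and equals each count over the library total on that scale. The deposited log2 table equals the log2 of the count plus 0.5 over an effective library size, 0.610 to 0.843 of the total. It holds 32704 of the 48526 genes. The 15822 genes it leaves out include 11754 with counts and carry 30.6% to 32.3% of the counts of a library, and 8602 of the genes it keeps have no count. The reason is not given in the sources used here, and all results come from the deposited counts. Of the 48526 genes 48058 matched a symbol of the GENCODE vM21 annotation of GRCm38, from which gene locations were taken (coordinates counted from 1). The 468 without a match held 0.058% of the counts. Of 398 genes under the naming rule, 113 share exon bases with another gene, where counts of a non-stranded library can come from either.

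Libraries were grouped by model, genotype, age and treatment from the labels and column names, and the animal number served as the replicate name. Animal numbers name different animals, and no library was left out. Library totals ran from 11050277 to 29651179 counts. Between replicates of a group, pairs of libraries differed by far more than counting error, with a chi-square per gene of 9.98 to 214. Per the labels, the inducible groups and their controls were exposed to 3 mg tamoxifen through the dam on embryonic day 13 and the constitutive groups were untreated. Sex was read from the counts of Xist and of genes on the Y chromosome.

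Each comparison used only its own groups, in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr, TMM scaling, quasi-likelihood fit with robust=TRUE, Benjamini-Hochberg adjustment and a threshold of 0.05. A gene rose or fell only when it passed. Standard errors are the log2 change over the square root of the F statistic. The 7 knockout comparisons set knockout against control at each age and model. The 3 model interactions subtract the inducible from the constitutive effect at an age, the 2 age interactions subtract the P0 from the 6-week effect, and the 2 maturation comparisons set controls at 6 weeks against P0. Shared calls are genes called in the same direction in both models, set against the product of the list sizes over the genes tested in both, with a one-sided Fisher exact test. Tests, groups, alternatives, gene lists and the naming rule were fixed before the data were examined, apart from the alternatives and the tests of the closing section that are named there as chosen after results were seen.

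Genes were named by a fixed rule. Hdac1, Hdac2 and Cx3cr1 are always named, then the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and every knockout library beyond every control, leaving out predicted and unnamed genes. From each list up to 4 called members with the smallest adjusted p are named. Interactions give the 5 smallest adjusted p-values, and maturation comparisons the 5 largest rises and falls. Where fewer than 3 genes were called, the 3 smallest p-values are named as not passing. Not every gene under the rule is printed, and some genes are not reported here. A fold against a group with 0 counts is a lower bound, with 3 counts over the group (the upper limit at 95% for a count of 0) in place of 0, and genes with 1 to 3 counts in a group get no fold. The 28 gene lists are the other histone deacetylases, the subunits of HDAC1 and HDAC2 complexes, DNA replication genes, mitosis genes, cyclin-dependent kinase inhibitors, p53 targets, pro-apoptotic genes, anti-apoptotic genes, homeostatic microglia genes, disease-associated microglia genes, type I interferon genes, inflammatory genes, antigen presentation genes, lysosome genes, cholesterol synthesis genes, immediate early genes, border macrophage markers, monocyte markers, neutrophil markers, lymphocyte markers, neuron markers, astrocyte markers, oligodendrocyte lineage markers, vascular markers, erythroid markers, ribosomal protein genes, nuclear respiratory chain genes and mitochondrially encoded genes. Each list with at least 3 tested members was tested with camera of limma 3.58.1 (preset correlation 0.01 between genes) on voom values, adjusted over the lists of a comparison, and again with an estimated correlation and with the fry rotation test. Members were written from general knowledge, so a list names genes typical of a state or cell type. List counts adjusted over all tested genes stand beside counts adjusted over the list alone.

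Alternatives were RLE size factors, limma-voom, DESeq2 1.42.0 (Wald test), no filter on low counts, a single fit over all 50 libraries, a sex term, and each replicate left out. After the data were seen, fits without inducible P0 control 56 and knockout 57 and a batch term for them were added. With a group of 2, leaving out 1 knockout at 2 weeks left a single knockout, taken to vary like the rest. Code was tested on simulated data with the dispersions of each comparison and 200 genes changed. Of genes changed 2-fold and 4-fold, the constitutive comparisons recovered 59% and 84% at P0, 44% and 77% at 2 weeks and 57% and 83% at 6 weeks, and the inducible ones 11% and 59% at E16, 45% and 82% at P0, 78% and 97% at 2 weeks and 69% and 94% at 6 weeks. Model interactions recovered 14% and 69% at P0, 53% and 81% at 2 weeks and 32% and 76% at 6 weeks, age interactions 17% and 64% (constitutive) and 22% and 70% (inducible), and maturation comparisons 55% and 91% and 50% and 84%. Files were read and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Raw reads were not used here, so exons and single transcripts were not measured.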

Results

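RNA-seq counts were analysed for 50 libraries of microglia sorted by flow cytometry from mice with loxP sites at both copies of Hdac1 and Hdac2, in 14 groups. Control mice carried no Cre, so in each knockout comparison an effect of the deletions cannot be told apart from an effect of carrying Cre. Constitutive knockouts carried Cx3cr1-Cre and were sampled at birth (P0), 2 weeks and 6 weeks. Inducible knockouts carried Cx3cr1-CreERT2, and they and their controls came from dams given tamoxifen on embryonic day 13. The inducible model was sampled on embryonic day 16 (E16), at P0, at 2 weeks and at 6 weeks. Control and knockout libraries numbered 4 and 3 (constitutive P0), 4 and 2 (constitutive 2 weeks), 4 and 3 (constitutive 6 weeks), 4 and 3 (E16), 3 and 4 (inducible P0), and 4 and 4 (inducible 2 weeks and 6 weeks). Each library came from a different animal and held 11050277 to 29651179 counts. Levels are CPM, the count per library total on the usual scale, as group means, and ± gives the standard error of a fitted log2 change.

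Hdac1 (GRCm38 chromosome 4, 129516104 to 129542713, minus strand) was not called in any of the 7 knockout comparisons, whereas Hdac2 (chromosome 10, 36974544 to 37001889, plus strand) fell in 4. Both encode class I histone deacetylases, and both are the targeted genes. In the constitutive model mean Hdac1 went from 12.4 to 18.3 CPM at P0 (log2 change 0.21 ± 0.42), 18.5 to 12.4 CPM at 2 weeks (-0.56 ± 0.24) and 15.6 to 37.1 CPM at 6 weeks (1.21 ± 0.88). The higher knockout means at P0 and 6 weeks came from single libraries. The library labelled knockout 68 (P0) held Hdac1 at 35.7 CPM, against 10.3 and 8.86 in the other knockouts. The library labelled knockout 380 (6 weeks) held 92.2 CPM, against 7.56 and 11.5. In the inducible model mean Hdac1 was lower at all ages, from 17.2 to 11.2 CPM at E16 (log2 change -0.74 ± 0.19), 13.4 to 8.36 CPM at P0 (-0.68 ± 0.23), 17.7 to 13.8 CPM at 2 weeks (-0.43 ± 0.13) and 15.6 to 11.99 CPM at 6 weeks (-0.41 ± 0.17), without a call.

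Hdac2 fell in constitutive knockouts at 6 weeks, from 69.4 to 29.7 CPM (log2 change -1.28 ± 0.25), and in inducible knockouts at P0, from 138 to 60.7 CPM (-1.19 ± 0.16), at 2 weeks, from 76.1 to 29.8 CPM (-1.42 ± 0.10), and at 6 weeks, from 70.6 to 29.6 CPM (-1.28 ± 0.12). It was not called in constitutive knockouts at P0 (144 to 151 CPM, log2 change -0.29 ± 0.18 after TMM scaling) or 2 weeks (67.0 to 55.6 CPM, -0.24 ± 0.23), nor at E16 (153 to 152 CPM, -0.20 ± 0.47). At E16 the library labelled knockout 1 held Hdac2 at 316 CPM, against 71.4 and 68.6 in the other knockouts and 133 to 165 in controls. At 2 weeks constitutive knockout 89 held Hdac2 at 70.1 CPM and knockout 80 at 41.0, with controls at 59.8 to 71.3. Counts of a targeted gene can include exons outside the deleted part, and the labels do not name the deleted exons.

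Cx3cr1 (chromosome 9, 119901616 to 120069879, minus strand), a fractalkine receptor gene that drives the Cre in both models, fell in 6 comparisons. Its level went from 3424 to 168 CPM in constitutive P0 knockouts (log2 change -4.70 ± 0.59), 6856 to 1997 CPM at 2 weeks (-1.79 ± 0.12) and 6613 to 3468 CPM at 6 weeks (-0.98 ± 0.25). In the inducible model it went from 2750 to 414 CPM at P0 (-2.71 ± 0.17), 6020 to 3355 CPM at 2 weeks (-0.91 ± 0.11) and 7620 to 3562 CPM at 6 weeks (-1.12 ± 0.12), and the change at E16 (2963 to 564 CPM, -2.47 ± 0.38) was not called. Esr1 (chromosome 10, 4611593 to 5005614, plus strand), the mouse estrogen receptor gene, is related to part of CreERT2. It rose in inducible knockouts alone, from 5.74 to 36.8 CPM at P0 (2.69 ± 0.23), 7.18 to 159.9 CPM at 2 weeks (4.40 ± 0.18) and 11.2 to 168 CPM at 6 weeks (3.87 ± 0.27). At E16 it went from 2.499 to 43.8 CPM (4.06 ± 0.45, not called), and in constitutive knockouts its log2 changes were -0.023 ± 0.35 at P0, -0.57 ± 0.30 at 2 weeks and 0.22 ± 0.22 at 6 weeks. Esr1 is described at E16, at P0 and in the constitutive model because it stood out at the later inducible ages, a choice made after the values were seen. Part of the Cx3cr1 exons is shared with Gm33858, so counts there can come from either gene.

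**Figure D1:**
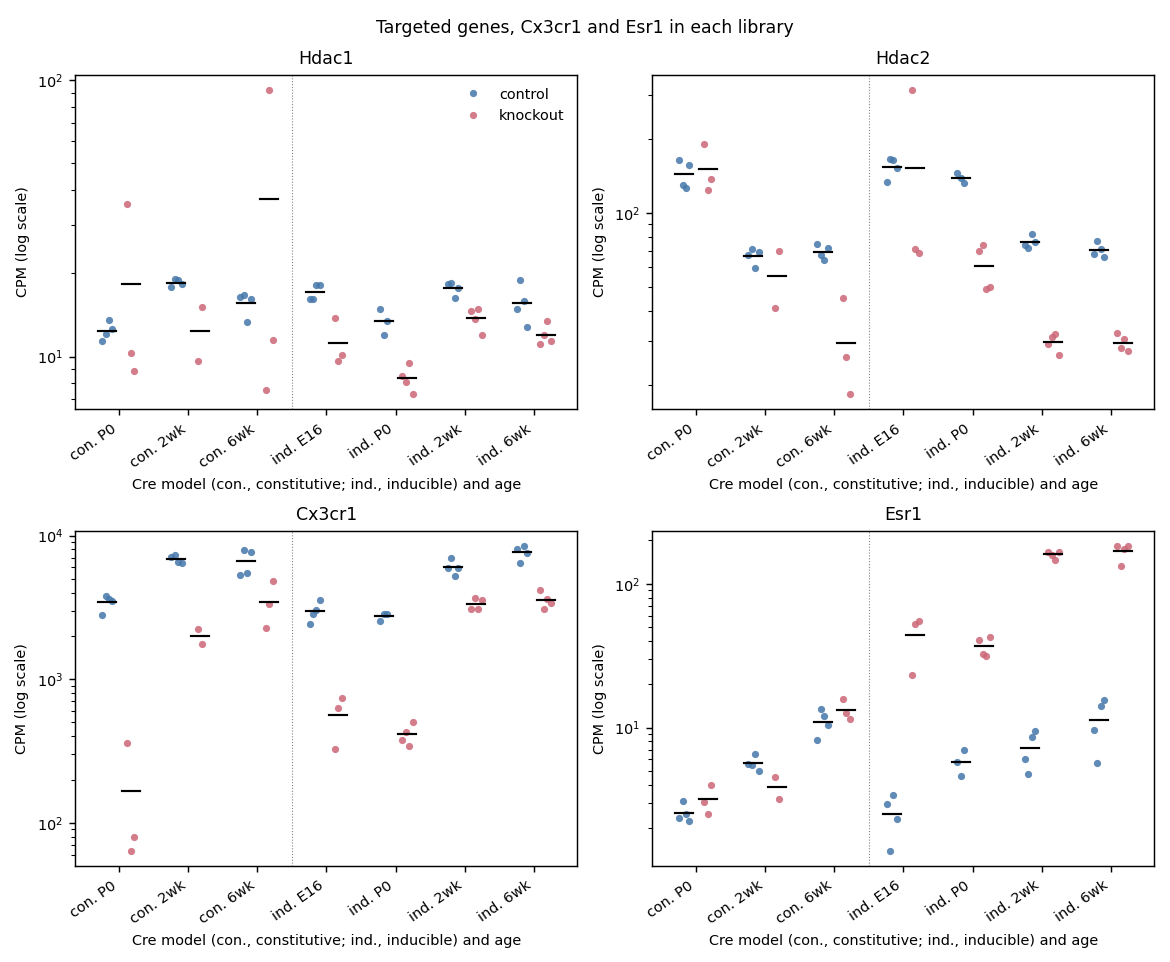
CPM (log axis) of Hdac1, Hdac2, Cx3cr1 and Esr1 in each library, by model and age. Each dot is a library, control or knockout by colour, and black bars are group means; Esr1 was chosen after its values were seen.

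The constitutive P0 comparison asked how sorted cells of knockouts differed from those of controls at birth, with 3 knockout and 4 control libraries. Among the largest losses were homeostatic microglia genes and others. Crybb1, a crystallin gene, fell 45.5-fold (log2 change -5.51 ± 1.12) and Fcrls 24.5-fold (log2 change -4.62 ± 0.45). The purinergic receptor gene P2ry12 fell 22.3-fold (log2 change -4.48 ± 0.60) and Cx3cr1 25.9-fold (log2 change -4.70 ± 0.59). Losses of similar size were Myadml2 (26.9-fold, log2 change -4.75 ± 0.60), Cryba4 (25.02-fold, log2 change -4.65 ± 0.61) and Liph (21.9-fold, log2 change -4.46 ± 0.39). Among the largest rises were Matn3 (19.6-fold, log2 change 4.30 ± 0.76), a cartilage matrix gene, Ms4a3 (19.1-fold, log2 change 4.25 ± 0.78) and Rab44 (16.3-fold, log2 change 4.03 ± 0.50). Mpo, which encodes myeloperoxidase, rose 15.0-fold (log2 change 3.90 ± 0.65), followed by Emp1 (9.68-fold, log2 change 3.27 ± 0.47). In all of these, every knockout library lay beyond every control library. By the edgeR test 3942 of 18411 genes rose and 3726 fell, with adjusted p = 0.00918 for Crybb1 and 8.25e-04 for Mpo. The library labelled knockout 68, with Hdac1 above every control, is among the 3 knockouts behind these directions, and it held Cx3cr1 at 359 CPM against 64.1 and 79.1. Without it the log2 changes were -7.84 for Crybb1, -6.26 for Cryba4, -5.94 for Cx3cr1, -5.87 for Myadml2, -5.78 for P2ry12, -5.40 for Fcrls, -5.12 for Liph and 2.87 for Mpo. Without control 71 that of Ms4a3 was 6.06, without control 74 that of Matn3 was 4.97, and without knockout 76 those of Matn3 and Rab44 were 3.63 and 3.21.

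Of the homeostatic microglia genes 28 of 28 fell (28 adjusted over the list alone, camera adjusted p = 1.28e-19, adjusted p = 0.342 with an estimated correlation). Among them were Sparc (log2 change -2.70 ± 0.20), Tgfbr1 (log2 change -2.65 ± 0.22), a TGF-beta receptor gene, and Cst3 (log2 change -2.21 ± 0.20). Of the lysosome genes 23 of 25 fell, 2 not called (23 adjusted over the list alone, camera adjusted p = 1.70e-15, adjusted p = 0.342 with an estimated correlation). Among them was Ctsh (log2 change -2.17 ± 0.14). Of the disease-associated microglia genes 2 of 23 rose and 18 fell, 3 not called (2 and 18 adjusted over the list alone, camera adjusted p = 9.58e-08, adjusted p = 0.391 with an estimated correlation). Members called included losses of Apoe (log2 change -2.53 ± 0.19), Igf1 (log2 change -2.21 ± 0.17) and Cd68 (log2 change -2.92 ± 0.25). For type I interferon genes 2 of 30 rose and 12 fell, 16 not called (2 and 12 adjusted over the list alone, camera adjusted p = 0.00162, adjusted p = 0.536 with an estimated correlation). Mx2 fell (log2 change -2.97 ± 0.37). For inflammatory genes 4 of 23 rose and 13 fell, 6 not called (4 and 14 adjusted over the list alone, camera adjusted p = 0.00168, adjusted p = 0.536 with an estimated correlation). Examples were Cd86 (log2 change -2.70 ± 0.26) and Ccl3 (log2 change -3.01 ± 0.34). Immediate early genes were lower too (11 of 21 fell, 10 not called, 12 adjusted over the list alone, camera adjusted p = 0.00923, adjusted p = 0.569 with an estimated correlation). Of the border macrophage markers, some of which fetal microglia share, 1 of 13 rose and 9 fell, 3 not called (1 and 9 adjusted over the list alone, camera adjusted p = 8.46e-04, adjusted p = 0.476 with an estimated correlation). Among them was Cbr2 (log2 change -2.98 ± 0.17). Of the ribosomal protein genes 1 of 81 rose and 29 fell, 51 not called (0 and 14 adjusted over the list alone, camera adjusted p = 3.04e-05, adjusted p = 0.536 with an estimated correlation).

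Markers of other cells were higher. Of the neutrophil markers 13 of 13 rose (13 adjusted over the list alone, camera adjusted p = 2.13e-08, adjusted p = 0.342 with an estimated correlation). Members called included Retnlg (log2 change 2.82 ± 0.23) and S100a9 (log2 change 2.65 ± 0.28). The sum of the list was 7920 to 12200 CPM in knockouts against 725 to 1710 in controls. Of the monocyte markers 10 of 12 rose, 2 not called (10 adjusted over the list alone, camera adjusted p = 1.39e-06, adjusted p = 0.342 with an estimated correlation). An example was Ccr2 (log2 change 1.81 ± 0.21). Of the neuron markers 16 of 16 rose (16 adjusted over the list alone, camera adjusted p = 2.93e-07, adjusted p = 0.404 with an estimated correlation). Of the astrocyte markers 13 of 13 rose (13 adjusted over the list alone, camera adjusted p = 2.93e-07, adjusted p = 0.342 with an estimated correlation). Oligodendrocyte lineage markers (8 of 13 rose and 1 fell, 4 not called, 8 and 1 adjusted over the list alone, camera adjusted p = 0.00518, adjusted p = 0.342 with an estimated correlation), vascular markers (9 of 14 rose, 5 not called, 10 adjusted over the list alone, camera adjusted p = 9.90e-04, adjusted p = 0.391 with an estimated correlation) and erythroid markers (8 of 8 rose, 8 adjusted over the list alone, camera adjusted p = 1.91e-04, adjusted p = 0.342 with an estimated correlation) were higher, with Olig1 (log2 change 1.74 ± 0.17), Flt1 (log2 change 2.06 ± 0.31) and Slc4a1 (log2 change 2.62 ± 0.42). Lymphocyte markers tested higher, with Cd79a (log2 change 2.19 ± 0.45) up and Cd79b (log2 change -1.48 ± 0.15) down (6 of 13 rose and 1 fell, 6 not called, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0202, adjusted p = 0.391 with an estimated correlation). The sum of homeostatic microglia genes was 3805 to 7842 CPM in knockouts and 29080 to 34750 in controls in the same libraries, and the summed neuron markers were 3758 to 4566 against 1066 to 2261. Of the cholesterol synthesis genes 12 of 20 rose and 1 fell, 7 not called (12 and 1 adjusted over the list alone, camera adjusted p = 8.78e-04, adjusted p = 0.432 with an estimated correlation). Among them were Srebf2 (log2 change 1.01 ± 0.14) and Sqle (log2 change 1.02 ± 0.16). Of the mitochondrially encoded genes 3 of 8 rose, 5 not called (6 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.536 with an estimated correlation).

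The lists of cell division and death were not called by the camera test at P0. For mitosis genes 2 of 28 fell, 26 not called (0 adjusted over the list alone, camera adjusted p = 0.112). For DNA replication genes 7 of 30 fell, 23 not called (6 adjusted over the list alone, camera adjusted p = 0.0838). Members called included Pcna (log2 change -0.77 ± 0.13) and Mcm3 (log2 change -0.86 ± 0.19). For the cyclin-dependent kinase inhibitors 3 of 6 rose and 1 fell, 2 not called (3 and 1 adjusted over the list alone, camera adjusted p = 0.120). For p53 targets 7 of 26 rose and 6 fell, 13 not called (7 and 8 adjusted over the list alone, camera adjusted p = 0.883). Fas rose (log2 change 1.70 ± 0.35). Pro-apoptotic genes (3 of 18 rose and 7 fell, 8 not called, 3 and 9 adjusted over the list alone, camera adjusted p = 0.0819) and anti-apoptotic genes (1 of 11 rose and 4 fell, 6 not called, 1 and 4 adjusted over the list alone, camera adjusted p = 0.0804) went both ways, with Casp8 (log2 change -2.14 ± 0.17), Bmf (log2 change -1.88 ± 0.24) and Cflar (log2 change -1.81 ± 0.19) down and Bcl2 (log2 change 0.59 ± 0.13) up. Among the other histone deacetylases 6 of 16 rose and 2 fell, 8 not called (6 and 2 adjusted over the list alone, camera adjusted p = 0.590). Hdac7 rose (log2 change 1.43 ± 0.23). Among the subunits of HDAC1 and HDAC2 complexes 2 of 26 rose and 6 fell, 18 not called (2 and 6 adjusted over the list alone, camera adjusted p = 0.801). Of the antigen presentation genes 5 of 18 rose and 6 fell, 7 not called (5 and 6 adjusted over the list alone, camera adjusted p = 0.581). Of the nuclear respiratory chain genes 6 of 70 rose and 7 fell, 57 not called (2 and 2 adjusted over the list alone, camera adjusted p = 0.728). Median, mean and test differed in sign for the subunits of HDAC1 and HDAC2 complexes and antigen presentation genes. With the library labelled knockout 68 left out, Hdac1 and Hdac2 passed the threshold as falls (Hdac1 log2 change -0.74).

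At 2 weeks the constitutive comparison (2 knockouts, 4 controls) asked how sorted juvenile cells differed. Sall3, a relative of the microglial factor gene Sall1, fell 389-fold (log2 change -8.60 ± 0.21), and Mrc2 (171-fold, log2 change -7.42 ± 0.62) and Ebf3 (136-fold) fell with it. The 8 largest named rises started from 0 counts in all 4 controls, and of these Sirpb1c rose at least 528-fold, Emp1 at least 448-fold, the co-stimulatory receptor gene Cd40 at least 427-fold and Cd209a at least 331-fold. These lower bounds cover counting error only. Apoe, an apolipoprotein gene (chromosome 7, 19696109 to 19699188, minus strand), rose 9.67-fold from 1569 to 15200 CPM (log2 change 3.27 ± 0.15), and Axl, a receptor kinase gene (chromosome 7, 25757273 to 25788705, minus strand), rose 19.9-fold (log2 change 4.31 ± 0.16). In total 3658 of 15017 genes rose and 2666 fell (edgeR, adjusted p = 5.03e-08 for Sall3 and 2.75e-07 for Axl), and both knockouts lay beyond all controls for each of the largest rises and falls. Of the 2 knockouts, 89 held Hdac2 within the range of the controls, and Hdac1 at 15.1 CPM and Cx3cr1 at 1762 CPM below those of all controls (17.9 to 19 and 6467 to 7273). The log2 change of Mrc2 was -10.51 without knockout 80 and -6.44 without knockout 89.

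Every tested member of the mitosis and DNA replication lists rose. Of the mitosis genes 28 of 28 rose (28 adjusted over the list alone, camera adjusted p = 4.71e-18, adjusted p = 0.282 with an estimated correlation). Among them were Mki67 (log2 change 2.05 ± 0.12), a proliferation marker, and Ccnb2 (log2 change 3.07 ± 0.18). Of the DNA replication genes 30 of 30 rose (30 adjusted over the list alone, camera adjusted p = 4.81e-14, adjusted p = 0.282 with an estimated correlation). Members called included Rrm1 (log2 change 1.78 ± 0.11). Of the p53 targets 12 of 25 rose and 1 fell, 12 not called (12 and 1 adjusted over the list alone, camera adjusted p = 0.0130, adjusted p = 0.542 with an estimated correlation). Examples were Cdkn1a (log2 change 1.72 ± 0.17) and Fas (log2 change 3.54 ± 0.46). Of the homeostatic microglia genes 1 of 28 rose and 25 fell, 2 not called (1 and 25 adjusted over the list alone, camera adjusted p = 1.45e-14, adjusted p = 0.276 with an estimated correlation). Among them were Tmem119 (log2 change -1.63 ± 0.13) and Selplg (log2 change -2.32 ± 0.15). Of the disease-associated microglia genes 13 of 23 rose and 3 fell, 7 not called (13 and 3 adjusted over the list alone, camera adjusted p = 0.00262, adjusted p = 0.289 with an estimated correlation). Members called included Spp1 (log2 change 3.40 ± 0.24) and Igf1 (log2 change 2.93 ± 0.18). Of the type I interferon genes 28 of 30 rose, 2 not called (28 adjusted over the list alone, camera adjusted p = 2.59e-10, adjusted p = 0.276 with an estimated correlation). An example was Bst2 (log2 change 2.41 ± 0.15). Of the antigen presentation genes 11 of 18 rose, 7 not called (11 adjusted over the list alone, camera adjusted p = 8.57e-04, adjusted p = 0.282 with an estimated correlation). Among them was Cd74 (log2 change 2.89 ± 0.15). Of the ribosomal protein genes 30 of 79 rose and 3 fell, 46 not called (30 and 3 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.610 with an estimated correlation). Of the nuclear respiratory chain genes 57 of 70 rose and 0 fell, 13 not called (61 and 1 adjusted over the list alone, camera adjusted p = 2.18e-14, adjusted p = 0.306 with an estimated correlation).

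Of the border macrophage markers 11 of 13 rose, 2 not called (11 adjusted over the list alone, camera adjusted p = 1.06e-07, adjusted p = 0.150 with an estimated correlation). Ms4a7 (chromosome 19, 11321039 to 11336146, minus strand) was up 209-fold (log2 change 7.71 ± 0.23), Pf4 up 282-fold (log2 change 8.14 ± 0.25) and Mrc1 up 10.1-fold (log2 change 3.34 ± 0.21). Of the monocyte markers 12 of 12 rose (12 adjusted over the list alone, camera adjusted p = 3.40e-08, adjusted p = 0.306 with an estimated correlation). Members called included Itga4 (log2 change 6.41 ± 0.20) and Ccr2 (log2 change 5.43 ± 0.35). Of the neutrophil markers 13 of 13 rose (13 adjusted over the list alone, camera adjusted p = 1.39e-07, adjusted p = 0.410 with an estimated correlation). Examples were S100a8 (log2 change 6.49 ± 1.08) and Ly6g (log2 change 6.48 ± 0.83). Without knockout 89 the log2 changes were 4.72 for Ccr2, 5.59 for S100a8 and 5.52 for Ly6g, without knockout 80 that of Ly6g was 7.07 and without control 81 that of S100a8 7.09. Summed neutrophil markers were 18970 and 54380 CPM in knockouts 80 and 89 against 121 to 889 in controls, and summed monocyte markers 10510 and 23720 against 199.6 to 485. The homeostatic sum was 34390 and 21770 CPM against 92380 to 102500, and which cells hold the list rises stays open.

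Lists without a camera call at 2 weeks held strong single changes. For inflammatory genes 8 of 21 rose and 8 fell, 5 not called (8 and 9 adjusted over the list alone, camera adjusted p = 0.780). Among them were Il1b (log2 change 4.05 ± 0.25) and Ccl7 (log2 change 2.86 ± 0.20) up. For immediate early genes 4 of 20 rose and 7 fell, 9 not called (5 and 7 adjusted over the list alone, camera adjusted p = 0.590). Members called included Jun (log2 change -1.73 ± 0.11) and Ier5 (log2 change -1.84 ± 0.15) down. The other 14 lists were not called either. Median, mean and test differed in sign for inflammatory genes, immediate early genes and astrocyte markers.

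At 6 weeks the constitutive comparison (3 knockouts, 4 controls) asked what remained in young adults. Apoe rose 67.96-fold, from 427 to 29990 CPM (log2 change 6.09 ± 0.46), Axl 32.1-fold (log2 change 5.00 ± 0.24) and the border macrophage gene Ms4a7 402-fold (log2 change 8.65 ± 0.47). Other large rises were Ms4a14 (346-fold, log2 change 8.43 ± 0.61), Hepacam2 (179-fold, log2 change 7.48 ± 1.17) and Pdpn (146-fold, log2 change 7.19 ± 0.63). Sall3 fell 35.9-fold (log2 change -5.17 ± 0.40), Hspb3 122-fold (log2 change -6.93 ± 0.41), Yes1 38.2-fold (log2 change -5.26 ± 0.88) and Elavl4 37.0-fold. Counts of calls were 975 up and 756 down of 14428 genes (edgeR, adjusted p = 1.82e-06 for Axl and 8.20e-05 for Apoe). The library labelled knockout 380, with Hdac1 at 92.2 CPM, is among the 3 knockouts behind these directions. Without it the calls dropped to 1153 and Hdac1 stood at a log2 change of -0.75 against 1.21 ± 0.88 with it. Without it the log2 change of Apoe was 5.47, a smaller rise, that of Hepacam2 6.49, that of Hspb3 -8.31 and that of Yes1 -8.73. Hepacam2 was 9.32 without control No_377 and Pdpn 8.62 without control No_396. The call of Cx3cr1 was lost when control No_377, control 400, knockout No_379 or knockout 380 was left out.

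Of the border macrophage markers 8 of 13 rose, 5 not called (8 adjusted over the list alone, camera adjusted p = 8.61e-10, adjusted p = 0.0833 with an estimated correlation). Among them were Mrc1 (log2 change 3.98 ± 0.23) and Siglec1 (log2 change 3.89 ± 0.30). Of the neutrophil markers 10 of 11 rose, 1 not called (10 adjusted over the list alone, camera adjusted p = 1.02e-13, adjusted p = 0.216 with an estimated correlation). Members called included Retnlg (log2 change 2.96 ± 0.28). Of the monocyte markers 7 of 12 rose, 5 not called (8 adjusted over the list alone, camera adjusted p = 2.43e-09, adjusted p = 0.241 with an estimated correlation). Examples were Ms4a4c (log2 change 4.001 ± 0.29) and Lyz2 (log2 change 3.58 ± 0.42). Summed monocyte markers were 4925 to 13360 CPM in knockouts and 463 to 1045 in controls, and summed border macrophage markers 2150 to 2938 and 580 to 996. Of the disease-associated microglia genes 8 of 23 rose and 2 fell, 13 not called (12 and 3 adjusted over the list alone, camera adjusted p = 7.06e-04, adjusted p = 0.241 with an estimated correlation). Among them was Clec7a (log2 change 2.77 ± 0.23). Of the type I interferon genes 19 of 30 rose, 11 not called (23 adjusted over the list alone, camera adjusted p = 1.45e-11, adjusted p = 0.216 with an estimated correlation). Members called included Slfn5 (log2 change 2.84 ± 0.38). Inflammatory genes (8 of 23 rose and 1 fell, 14 not called, 8 and 3 adjusted over the list alone, camera adjusted p = 0.0471, adjusted p = 0.241 with an estimated correlation) included Il1b (log2 change 2.14 ± 0.28), and antigen presentation genes were higher (3 of 17 rose, 14 not called, 8 adjusted over the list alone, camera adjusted p = 5.15e-04, adjusted p = 0.241 with an estimated correlation). Homeostatic microglia genes tested lower (15 of 28 fell, 13 not called, 19 adjusted over the list alone, camera adjusted p = 1.17e-13, adjusted p = 0.216 with an estimated correlation). An example was Adgrg1 (log2 change -1.33 ± 0.19). The sum of the list was 59280 to 83180 CPM against 101200 to 109400. Of the mitosis genes 10 of 28 rose, 18 not called (15 adjusted over the list alone, camera adjusted p = 1.58e-09, adjusted p = 0.216 with an estimated correlation). Among them were Cenpf (log2 change 1.86 ± 0.22) and Mki67 (log2 change 1.58 ± 0.29). Of the DNA replication genes 3 of 30 rose, 27 not called (7 adjusted over the list alone, camera adjusted p = 0.00607, adjusted p = 0.276 with an estimated correlation). Rrm2 rose (log2 change 1.84 ± 0.32). Of the ribosomal protein genes, which tested higher, 1 of 78 fell, 77 not called (1 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.790 with an estimated correlation). Signs of median, mean and test differed for the subunits of HDAC1 and HDAC2 complexes, pro-apoptotic genes, cholesterol synthesis genes, immediate early genes, neuron markers and astrocyte markers.

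**Figure D2:**
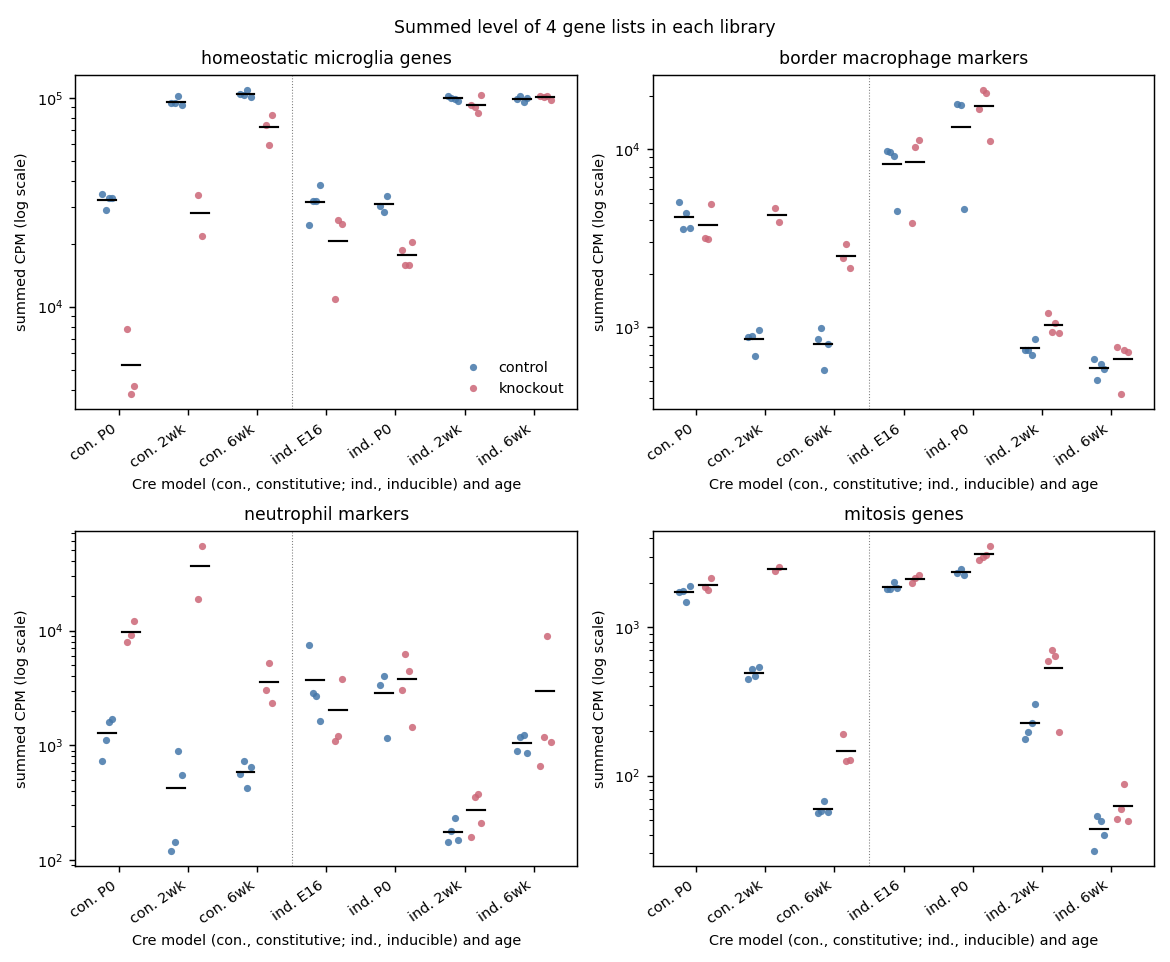
Summed CPM (log axis) of homeostatic microglia, border macrophage, neutrophil and mitosis genes in each library, by model and age. Each dot is a library, control or knockout by colour, and black bars are group means.

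The E16 comparison of the inducible model (3 knockouts, 4 controls) asked what changed in the days after tamoxifen. No gene passed, and edgeR called 0 of 17594 genes, with 2306 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0799. DESeq2 called 881 and limma-voom 0. The lowest p-values, none passing, were those of Cd300c2 (log2 change -2.24 ± 0.23), Gpr137b (log2 change -1.53 ± 0.16), a lysosomal membrane gene, and Rcn1 (log2 change 1.47 ± 0.16), each with adjusted p = 0.0799. The library labelled knockout 1 held Hdac2 above every control, a summed erythroid level of 13370 CPM against 747 to 1025 in the other knockouts, neuron markers of 3977 against 481 to 751 and homeostatic genes of 10870 against 24980 to 26130. Control 2 held monocyte markers of 13440 CPM against 2408 to 3116 in the other controls. Without the library labelled knockout 1, 638 genes were called, among them Hdac2, Cx3cr1, Cd300c2, Gpr137b and Rcn1.

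At E16 no list member was called over all genes, yet the camera test placed 5 lists higher and 9 lower. None held with an estimated correlation, and 1 of the 14 held in the fry rotation test (the subunits of HDAC1 and HDAC2 complexes). Higher were DNA replication genes (0 of 30, 0 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.695 with an estimated correlation) and p53 targets (0 of 26, 1 adjusted over the list alone, camera adjusted p = 0.0406, adjusted p = 0.695 with an estimated correlation). Lower were homeostatic microglia genes (0 of 28, 3 adjusted over the list alone, camera adjusted p = 1.04e-08, adjusted p = 0.695 with an estimated correlation) and disease-associated microglia genes (0 of 23, 1 higher and 6 lower adjusted over the list alone, camera adjusted p = 1.33e-05, adjusted p = 0.695 with an estimated correlation). Median, mean and test differed in sign for pro-apoptotic genes, oligodendrocyte lineage markers and vascular markers.

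The inducible P0 comparison (4 knockouts, 3 controls) asked how knockouts induced at E13 differed from controls at birth. Large falls were Ecscr (9.60-fold, log2 change -3.26 ± 0.41), Crybb1 (7.47-fold, log2 change -2.90 ± 0.43) and Slamf8 (6.82-fold, log2 change -2.77 ± 0.36). With them fell Atp8a2 (6.69-fold, log2 change -2.74 ± 0.30), Cx3cr1 (6.55-fold, log2 change -2.71 ± 0.17) and the integrin gene Itgax (6.29-fold, log2 change -2.65 ± 0.32). Large rises were Mrgpra2a (36.3-fold, log2 change 5.18 ± 0.55), Fabp4 (20.4-fold, log2 change 4.35 ± 0.71), a fatty acid binding protein gene, Matn3 (10.4-fold, log2 change 3.37 ± 0.44) and Ttn (9.97-fold, log2 change 3.32 ± 0.36), the last a sarcomere gene. Matn3, Crybb1 and Cx3cr1 went the same way in constitutive knockouts at P0. Counts of calls were 1197 up and 626 down of 17573 genes (edgeR, adjusted p = 0.00690 for Crybb1 and 0.00127 for Matn3). The calls dropped to 680 without control 55, 960 without control 56, 999 without knockout 49 and 1063 without control 54. All 3 controls were male and 2 of 4 knockouts female, and with sex in the model 705 genes were called, against 2911 with DESeq2. Control 56 and knockout 57 held immediate early sums of 7437 and 7027 CPM, against 1826 to 2519 in the other controls and 1206 to 1414 in the other knockouts. Their sums were lower for border macrophage (4591 and 11110, against 17660 to 17940 and 16810 to 21570), neutrophil (1155 and 1442, against 3341 to 4009 and 3036 to 6202) and monocyte markers (1271 and 1240, against 2852 to 2966 and 2291 to 3433). Leaving both out, an alternative chosen after the data were seen, left 1149 calls. The log2 change of Mrgpra2a was 6.25 without control 55 and that of Fabp4 3.49 without knockout 57.

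Of the homeostatic microglia genes 0 of 28 rose and 14 fell, 14 not called (1 and 18 adjusted over the list alone, camera adjusted p = 6.93e-12, adjusted p = 0.446 with an estimated correlation). Among them were Adgrg1 (log2 change -2.65 ± 0.19), an adhesion receptor gene, P2ry12 (log2 change -1.45 ± 0.16) and Slc2a5 (log2 change -1.89 ± 0.24). Of the p53 targets 9 of 26 rose, 17 not called (13 adjusted over the list alone, camera adjusted p = 9.77e-06, adjusted p = 0.245 with an estimated correlation). Members called included Zmat3 (log2 change 2.14 ± 0.25), Phlda3 (log2 change 1.77 ± 0.26), Cdkn1a (log2 change 1.62 ± 0.24), a cell cycle inhibitor gene, and Ccng1 (log2 change 1.12 ± 0.17). Of the pro-apoptotic genes 5 of 19 rose, 14 not called (5 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.446 with an estimated correlation). Fas rose (log2 change 2.06 ± 0.35). DNA replication genes (13 of 30 rose, 17 not called, 20 adjusted over the list alone, camera adjusted p = 1.31e-11, adjusted p = 0.275 with an estimated correlation) and mitosis genes (7 of 28 rose, 21 not called, 14 adjusted over the list alone, camera adjusted p = 1.74e-08, adjusted p = 0.446 with an estimated correlation) tested higher, with Chaf1b (log2 change 1.21 ± 0.15), Mcm6 (log2 change 0.90 ± 0.13) and Ccnb2 (log2 change 0.90 ± 0.13). HDAC1 and HDAC2 complex subunits tested higher (4 of 26 rose, 22 not called, 5 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.446 with an estimated correlation). Examples were Sin3a (log2 change 1.21 ± 0.14) and Rbbp7 (log2 change 0.69 ± 0.13). Of the disease-associated microglia genes 2 of 23 rose and 9 fell, 12 not called (2 and 10 adjusted over the list alone, camera adjusted p = 4.58e-04, adjusted p = 0.446 with an estimated correlation). Among them were Cd9 (log2 change -1.53 ± 0.18) and Trem2 (log2 change -1.68 ± 0.23) down and Axl (log2 change 1.55 ± 0.19) up. Inflammatory genes were lower (1 of 24 rose and 3 fell, 20 not called, 1 and 3 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.446 with an estimated correlation). Nuclear respiratory chain genes tested higher (21 of 70 rose, 49 not called, 41 adjusted over the list alone, camera adjusted p = 9.05e-14, adjusted p = 0.446 with an estimated correlation), and Cox6b2 led them (log2 change 3.11 ± 0.35). The camera test also placed markers of other cells lower, namely neuron markers (0 of 16 fell, 0 adjusted over the list alone, camera adjusted p = 8.09e-04, adjusted p = 0.581 with an estimated correlation), astrocyte markers (1 of 13 fell, 0 adjusted over the list alone, camera adjusted p = 0.0282, adjusted p = 0.738 with an estimated correlation) and oligodendrocyte lineage markers (2 of 12 fell, 3 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.446 with an estimated correlation). It placed lysosome genes (1 of 25 rose and 2 fell, 1 and 2 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.695 with an estimated correlation) and immediate early genes (1 of 21 fell, 0 adjusted over the list alone, camera adjusted p = 0.0249, adjusted p = 0.765 with an estimated correlation) lower and ribosomal protein genes (2 of 81 rose, 1 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.738 with an estimated correlation) higher. Of the 15 list calls 5 held in the fry rotation test, those of homeostatic genes, p53 targets, pro-apoptotic genes, DNA replication genes and complex subunits. Signs of median, mean and test differed for type I interferon genes, lymphocyte markers and vascular markers.

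At 2 weeks the inducible comparison (4 knockouts, 4 controls) asked how much of the change persisted in juvenile mice. Esr1 rose 21.1-fold (log2 change 4.40 ± 0.18) and Hdac2 fell 2.68-fold (log2 change -1.42 ± 0.10). Among other rises were Trerf1, a transcriptional regulator gene (chromosome 17, 47140875 to 47361958, plus strand; 5.07-fold, log2 change 2.34 ± 0.31), Cdc42ep1 (5.65-fold, log2 change 2.499 ± 0.36), Htra3 (3.72-fold, log2 change 1.90 ± 0.22) and Axl (3.53-fold, log2 change 1.82 ± 0.24). Falls included the chemokine gene Ccl4 (2.53-fold, log2 change -1.34 ± 0.23), Liph (2.51-fold, log2 change -1.33 ± 0.11) and the histone gene Hist1h3e (3.84-fold, log2 change -1.94 ± 0.30), a member of a multigene family whose counts can mix. Calls numbered 155 up and 158 down of 13921 genes (edgeR, adjusted p = 5.84e-09 for Esr1 and 6.89e-04 for Trerf1), and every knockout lay beyond every control for the genes named so far. This count moved with single libraries: 94 without knockout 13, 112 without knockout 16 and 115 without control 1. It was 130 without knockout 10, 151 without control 3 and 938 without knockout 6. Knockout 6 was the only female knockout, and the controls were all female. With sex in the model 19 genes were called.

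Mitosis genes tested higher, and 6 of 28 rose, 22 not called (28 adjusted over the list alone, camera adjusted p = 3.38e-18, adjusted p = 0.437 with an estimated correlation). Examples were Cenpa (log2 change 0.87 ± 0.17) and Kif23 (log2 change 1.62 ± 0.31). DNA replication genes tested higher with no member called over all genes (0 of 30 rose, 30 not called, 9 adjusted over the list alone, camera adjusted p = 3.29e-09, adjusted p = 0.492 with an estimated correlation). The mitosis sum was 199 CPM in the female knockout 6, 598 to 701 in the male knockouts and 177 to 306 in controls. Border macrophage markers (3 of 11 rose, 8 not called, 5 adjusted over the list alone, camera adjusted p = 6.55e-06, adjusted p = 0.437 with an estimated correlation) included Dab2 (log2 change 0.77 ± 0.14) and Cd163 (log2 change 2.19 ± 0.43), and neutrophil markers (2 of 11 rose, 9 not called, 3 adjusted over the list alone, camera adjusted p = 1.40e-04, adjusted p = 0.437 with an estimated correlation) included Mmp9 (log2 change 1.83 ± 0.39). Homeostatic microglia genes (1 of 28 fell, 27 not called, 2 adjusted over the list alone, camera adjusted p = 0.00394, adjusted p = 0.492 with an estimated correlation), inflammatory genes (3 of 19 fell, 16 not called, 5 adjusted over the list alone, camera adjusted p = 0.00905, adjusted p = 0.437 with an estimated correlation), immediate early genes (0 of 20 rose and 4 fell, 16 not called, 1 and 7 adjusted over the list alone, camera adjusted p = 3.30e-04, adjusted p = 0.437 with an estimated correlation) and oligodendrocyte lineage markers (0 of 6 fell, 1 adjusted over the list alone, camera adjusted p = 0.0455, adjusted p = 0.437 with an estimated correlation) tested lower, with Btg2 (log2 change -0.67 ± 0.11). Apoe rose 2.06-fold (log2 change 1.05 ± 0.18), the p53 target Cdkn1a too (log2 change 0.97 ± 0.20) and Pf4 4.95-fold (log2 change 2.31 ± 0.52). The calls of Cenpa, Kif23, Cdkn1a and Pf4 each ended when a single library was left out, and that of Apoe ended without control 1 or knockout 10. None of the 8 list calls held in the fry rotation test. The median, the mean and the test had different signs for the other histone deacetylases, the subunits of HDAC1 and HDAC2 complexes, pro-apoptotic genes, type I interferon genes, vascular markers and erythroid markers.

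At 6 weeks the inducible comparison (4 knockouts, 4 controls) asked what was left in young adults, and few genes differed. Esr1 rose 14.7-fold (log2 change 3.87 ± 0.27), Serpinf1, the gene of a secreted serpin (chromosome 11, 75409769 to 75422701, minus strand), 3.12-fold (log2 change 1.64 ± 0.15), and the cohesin gene Stag3 3.82-fold (log2 change 1.94 ± 0.24). Stox2 (4.28-fold, log2 change 2.10 ± 0.33), Trps1 (4.14-fold, log2 change 2.05 ± 0.29) and Trerf1 (3.72-fold, log2 change 1.90 ± 0.28) rose too, and Hdac2 (2.43-fold, log2 change -1.28 ± 0.12) and Cx3cr1 (2.18-fold, log2 change -1.12 ± 0.12) fell. With Sorbs3 up (log2 change 2.25 ± 0.36), 7 genes rose and 2 fell of 14217 (edgeR, adjusted p = 2.55e-04 for Serpinf1 and 0.00134 for Cx3cr1). The calls of Stox2, Trps1 and Trerf1 were lost without single libraries, among them control 1, where 5 calls were left, and without knockout 4 calls reached 18. No list member was called over all genes. The camera test placed 1 list higher and 6 lower, among them mitosis genes (0 of 25, 0 adjusted over the list alone, camera adjusted p = 0.00120, adjusted p = 0.569 with an estimated correlation) higher and inflammatory genes (0 of 19, 0 adjusted over the list alone, camera adjusted p = 0.00120, adjusted p = 0.558 with an estimated correlation) lower, and none of the 7 held in the fry rotation test. Knockout 6 held summed neutrophil markers of 8898 CPM and monocyte markers of 2080, against 660.2 to 1172 and 388 to 482 in the other knockouts. Signs of median, mean and test differed for the other histone deacetylases, p53 targets, anti-apoptotic genes, oligodendrocyte lineage markers and ribosomal protein genes.

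**Figure D3:**
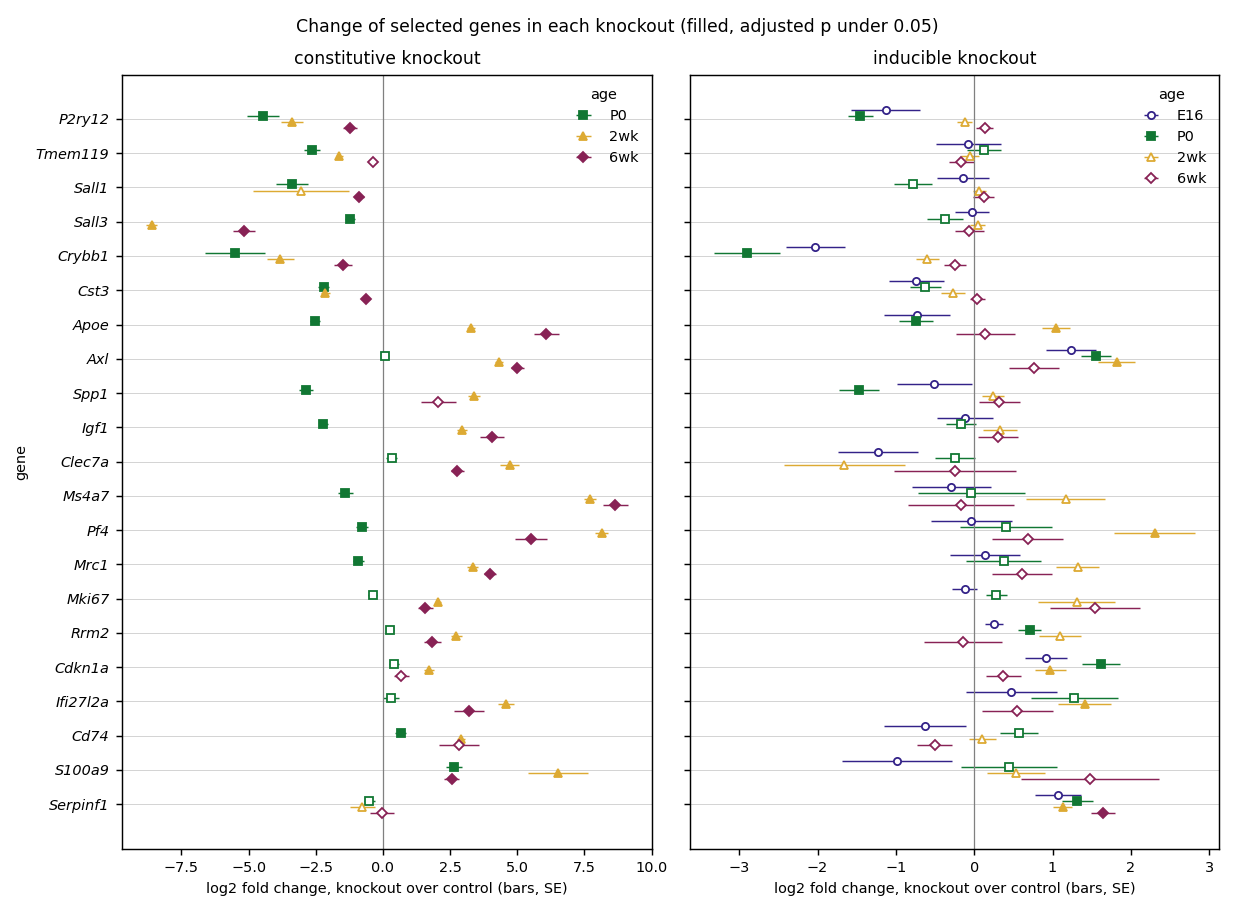
Log2 change (knockout against control, ± standard error) of selected genes at each age, for the constitutive and the inducible model. Filled points had an adjusted p under 0.05, and the genes were chosen after their values were seen.

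The model interactions asked where the constitutive knockout effect differed from the inducible one at the same age, as constitutive minus inducible. At P0 genes with the smallest adjusted p-values (edgeR) included Pon3, a paraoxonase gene, Gtf2h2 and Xlr. Their values, followed by the constitutive and the inducible log2 change, were Pon3 (log2 difference -2.56 ± 0.24, changes -2.25 ± 0.19 and 0.34 ± 0.15), Gtf2h2 (log2 difference -1.93 ± 0.19, changes -2.04 ± 0.14 and -0.070 ± 0.15) and Xlr (log2 difference -3.04 ± 0.28, changes -3.47 ± 0.21 and -0.40 ± 0.21), with adjusted p = 5.62e-05 for Pon3. At 2 weeks leading genes were Sall3 (log2 difference -8.66 ± 0.23, changes -8.60 ± 0.21 and 0.046 ± 0.10), Sgce (log2 difference -4.54 ± 0.17, changes -4.69 ± 0.17 and -0.17 ± 0.090) and Plxna4 (log2 difference -3.92 ± 0.20, changes -4.004 ± 0.18 and -0.10 ± 0.10), followed by Yes1 (log2 difference -4.63 ± 0.25) and the integrin gene Itga4 (log2 difference 5.88 ± 0.33), with adjusted p = 2.56e-14 for Sall3. At 6 weeks leading genes were Myo6 (log2 difference -4.53 ± 0.22, changes -4.54 ± 0.20 and -0.0010 ± 0.14) and Nbea (log2 difference -4.66 ± 0.26, changes -4.60 ± 0.19 and 0.073 ± 0.16), followed by Arhgap15 (log2 difference 5.02 ± 0.37), with adjusted p = 8.57e-10 for Myo6.

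In total 2692 genes had a higher and 3254 a lower effect in the constitutive model at P0 (of 19236), 2643 and 2343 at 2 weeks (of 15965) and 394 and 373 at 6 weeks (of 15492). The share of higher effects at P0 depended on scaling, 45.3% with TMM and 55.2% with RLE size factors, where the all-gene median moved from -0.035 to 0.087. Without constitutive knockout 73 the P0 count dropped to 3842. Model and treatment differ together here, since only the inducible groups received tamoxifen, and the libraries labelled knockout 68 (P0) and knockout 380 (6 weeks) enter these values.

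The age interactions asked whether the knockout effect at 6 weeks differed from that at P0. In the constitutive model Apoe, -2.53 ± 0.19 at P0, was 6.09 ± 0.46 at 6 weeks (log2 difference 8.60 ± 0.50, 7.99 without the library labelled knockout 380), and Axl went from 0.085 ± 0.12 to 5.00 ± 0.24 (log2 difference 4.89 ± 0.27). The ceruloplasmin gene Cp (log2 difference 5.57 ± 0.28) and Cd83 (log2 difference 3.60 ± 0.21) also shifted upward and Myo6 (log2 difference -4.77 ± 0.24) downward, with adjusted p = 2.59e-08 for Apoe (edgeR). Effects were higher at 6 weeks for 2780 genes and lower for 995 of 19214. That split depended on scaling, 73.6% higher with TMM and 59.8% with RLE size factors, where the all-gene median moved from 0.12 to -0.070. The libraries labelled knockout 68 and knockout 380 enter it. In the inducible model the fall of Adgrg1, -2.65 ± 0.19 at P0, was -0.18 ± 0.15 at 6 weeks (log2 difference 2.51 ± 0.25), and Itgam, an integrin gene, went from -2.23 ± 0.14 to 0.072 ± 0.10 (log2 difference 2.36 ± 0.14). Cd300c2 (log2 difference 2.08 ± 0.17) moved upward, and Klk8 (log2 difference -2.67 ± 0.22) and Tpm2 (log2 difference -3.22 ± 0.35) downward, with adjusted p = 4.91e-08 for Itgam. Here 284 genes were higher and 190 lower of 18516. The count was 254 without P0 control 55, 273 without 6-week control 10, 301 without 6-week control 5, 305 without P0 control 56 and 314 without 6-week knockout 9.

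Control maturation asked how the sorted cells of controls changed from P0 to 6 weeks (4 and 4 constitutive, 3 and 4 inducible libraries). In the constitutive controls the homeostatic gene Selplg rose 19.4-fold (log2 change 4.28 ± 0.11), Cst3 8.16-fold (log2 change 3.03 ± 0.13), Tmem119 (chromosome 5, 113793729 to 113800516, minus strand) 7.98-fold (log2 change 3.00 ± 0.16) and Adgrg1 6.95-fold (log2 change 2.80 ± 0.12). Duoxa1 rose at least 126-fold from 0 counts at P0, and Upk1b (224-fold, log2 change 7.81 ± 0.35) and Tgm2 (43.2-fold, log2 change 5.43 ± 0.22) followed. Spp1 fell 89.03-fold (log2 change -6.48 ± 0.25), Apoe 17.7-fold (log2 change -4.14 ± 0.21), and Igf1 56.2-fold (log2 change -5.81 ± 0.31). The proliferation gene Mki67 fell 31.0-fold (log2 change -4.95 ± 0.16), Top2a 31.3-fold (log2 change -4.97 ± 0.19) and Mrc1 19.8-fold (log2 change -4.30 ± 0.24). In the inducible controls Selplg rose 17.1-fold (log2 change 4.10 ± 0.15) and Cst3 7.85-fold (log2 change 2.97 ± 0.15). Spp1 fell 226-fold, Apoe 16.1-fold, Igf1 56.7-fold and Fabp5 50.9-fold. By edgeR 4612 genes rose and 5946 fell of 16535 in the constitutive and 3457 and 5336 of 16515 in the inducible controls, with adjusted p = 1.87e-10 and 2.42e-08 for Selplg.

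Lists are given for constitutive and then inducible controls, where 18 and 19 of 28 lists were called (4 and 3 higher). Of the homeostatic microglia genes 27 of 28 rose and 1 fell (27 and 1 adjusted over the list alone, camera adjusted p = 4.19e-15, adjusted p = 0.160 with an estimated correlation) and 25 of 28 rose and 1 fell, 2 not called (25 and 1 adjusted over the list alone, camera adjusted p = 4.86e-14, adjusted p = 0.0982 with an estimated correlation). Of the mitosis genes 28 of 28 fell (28 adjusted over the list alone, camera adjusted p = 9.41e-13, adjusted p = 0.160 with an estimated correlation) and 28 of 28 fell (28 adjusted over the list alone, camera adjusted p = 6.20e-15, adjusted p = 0.156 with an estimated correlation). Of the DNA replication genes 30 of 30 fell (30 adjusted over the list alone, camera adjusted p = 1.49e-10 and 0.0387 with an estimated correlation) and 30 of 30 fell (30 adjusted over the list alone, camera adjusted p = 5.10e-12, adjusted p = 0.0982 with an estimated correlation), the constitutive list being the only one of this comparison whose call held with an estimated correlation. Border macrophage markers were lower, 12 of 13 fell, 1 not called (12 adjusted over the list alone, camera adjusted p = 9.88e-06, adjusted p = 0.305 with an estimated correlation) and 13 of 13 fell (13 adjusted over the list alone, camera adjusted p = 5.87e-05, adjusted p = 0.431 with an estimated correlation). Examples were Dab2 (log2 change -3.71 ± 0.17) and Folr2 (log2 change -6.21 ± 0.48). The median, the mean and the test had different signs for the other histone deacetylases, p53 targets, pro-apoptotic genes and lysosome genes in the constitutive and the other histone deacetylases, pro-apoptotic genes, inflammatory genes and lysosome genes in the inducible controls. P0 pups were decapitated and older mice perfused, so age and handling cannot be told apart here.

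Shared calls asked which genes changed alike in both models at the same age. At 6 weeks they were 6 genes: Stag3 (log2 changes 2.31 and 1.94), Sorbs3 (log2 changes 5.18 and 2.25), Trps1 (log2 changes 4.89 and 2.05) and Trerf1 (log2 changes 3.16 and 1.90) rose in the constitutive and the inducible model, and Cx3cr1 (log2 changes -0.98 and -1.12) and Hdac2 (log2 changes -1.28 and -1.28) fell, against 0.522 expected. At 2 weeks 94 genes rose in both (expected 33.5, one-sided Fisher exact p = 2.81e-26) and 74 fell in both (expected 29.8, Fisher exact p = 7.00e-16), among them Axl (log2 changes 4.31 and 1.82), Apoe (log2 changes 3.27 and 1.05), Pf4 (log2 changes 8.14 and 2.31), Liph (log2 changes -6.14 and -1.33) and Cx3cr1 (log2 changes -1.79 and -0.91). At P0 413 genes fell in both (expected 137, Fisher exact p = 5.12e-130), for example Crybb1 (log2 changes -5.51 and -2.90), P2ry12 (log2 changes -4.48 and -1.45) and Adgrg1 (log2 changes -0.63 and -2.65), whereas the 259 that rose in both, for example Matn3 (log2 changes 4.30 and 3.37), compared with 257 expected (Fisher exact p = 0.445). A further 216 genes were called in opposite directions at P0, against 394 expected. Genes are not independent of each other, so these p-values overstate the evidence. With a sex term 7 shared calls were left at 2 weeks and 339 at P0. The shared count at 2 weeks was 58 without inducible knockout 13 or 16, 72 without knockout 10, 59 without control 1, 84 without control 3 and 543 without knockout 6. At P0 it was 390 without inducible control 55, 394 without control 54 and 445 without knockout 49, and at 6 weeks 3 without inducible control 1 or knockout 9.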

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

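The tests of the 3 patterns in this part were chosen only after the result was seen.

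The homeostatic list tested lower in all constitutive comparisons while sums of neutrophil, monocyte or border macrophage markers were higher. A lower share of microglia among the sorted cells, as the whole cause, would lower genes restricted to microglia by the same factor. Of 12 such genes, 33.3% at P0, 66.7% at 2 weeks and 50% at 6 weeks had a 95% interval that leaves out their median. These normal intervals are too narrow for small groups, so P0 stays open. Later ages argue against dilution by cells lacking all 12 as the whole cause. Other or partial dilution or a mix with undeleted cells stays open.

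Esr1 rose and Cx3cr1 fell in inducible knockouts after E16. Constitutive knockouts at 6 weeks (Esr1 log2 change 0.22) had no lower mean Hdac1. A rise of Esr1 from losing both Hdac1 and Hdac2 stays open. Reads of the Cre-ERT2 coding sequence counted at Esr1 remain possible, with a lowest lower 95% bound of 2.25 over the 4 inducible comparisons and Esr1 in knockouts at 7.05% to 8.42% of the Cx3cr1 level at E16, 7.58% to 10.8% at P0, 4.30% to 5.43% at 2 weeks and 4.31% to 5.40% at 6 weeks, so the ratio was not constant over age. Replacement of 1 Cx3cr1 copy by Cre predicts a log2 change near -1 and is excluded as the whole cause at E16 (-2.47) and P0 (-2.71), while the values at 2 weeks (-0.91) and 6 weeks (-1.12) match it.

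Mitosis genes were higher in inducible knockouts at 2 weeks, where 3 of 4 knockouts were male and all controls female. Over 16 controls of groups with both sexes the median male minus female log2 difference was 0.0427, against a knockout rise of 1.21. This argues against a sex difference common to all ages, but with 1 such female at 2 weeks that age stays open. So does sex dependence in knockouts: with a sex term the median was -0.22 and 0 members were called. Controls of 1 litter or exact age that cycle less cannot be told apart from a knockout effect, since constitutive over inducible controls gave a ratio of 2.19 at 2 weeks, close to the knockout over control ratio of 2.35.

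Single libraries far from the other 3 of their group were searched in 9 groups of 4 over 33 measures, 297 tests of which chance gives about 1 in 20, here 14.9, and 29 were found. Values are CPM, with the lowest and highest of the other 3 in parentheses. Constitutive controls at 2 weeks: library 77, p53 targets 1054 (1139 to 1156) and respiratory chain 4116 (3584 to 3654), library 81, homeostatic genes 102500 (92380 to 94100). Constitutive controls at 6 weeks: library No_396, Hdac1 13.4 (16.1 to 16.6), mitosis 67.5 (56.2 to 57.9) and p53 targets 1281 (1584 to 1636), library No_376, disease-associated genes 19070 (17590 to 17820), library 400, respiratory chain 3623 (3852 to 3860). Constitutive P0 control 70 had vascular markers of 272 (158 to 176). Inducible controls at 2 weeks: library 4, DNA replication 467 (375.7 to 384), library 2, cholesterol synthesis 332 (411 to 426). Inducible controls at 6 weeks: library 5, pro-apoptotic genes 971 (939 to 942), library 1, monocyte markers 587 (488 to 502), library 11, oligodendrocyte markers 148 (122 to 126). Controls at E16: library 5, mitosis 2037 (1816 to 1850), library 6, border macrophage markers 4511 (9163 to 9758) and oligodendrocyte markers 118 (152 to 154), library 2, monocyte markers 13440 (2408 to 3116). Inducible knockouts at 2 weeks: library 10, antigen presentation 1874 (2143 to 2189), library 6, vascular markers 44.3 (39.8 to 40.2). Inducible knockouts at 6 weeks: library 4, Esr1 133 (174 to 183) and border macrophage markers 422 (727 to 775), library 12, p53 targets 1710 (1485 to 1517), library 6, monocyte 2080 (388 to 482) and neutrophil markers 8898 (660.2 to 1172). Inducible knockouts at P0: library 57, kinase inhibitors 339 (204 to 218), anti-apoptotic genes 1048 (686 to 745) and immediate early genes 7027 (1206 to 1414), library 53, ribosomal protein genes 7087 (5015 to 5239).

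Differences between effects were called by an interaction test for 5946 genes (models at P0), 4986 (2 weeks), 767 (6 weeks), 3775 (ages, constitutive) and 474 (ages, inducible). The log2 differences of leading genes were Pon3 -2.56, Gtf2h2 -1.93, Gm49342 -2.51 and Xlr -3.04 between models at P0, Sall3 -8.66, Sgce -4.54, Plxna4 -3.92, Yes1 -4.63 and Itga4 5.88 at 2 weeks and Myo6 -4.53, Nbea -4.66, Hspb3 -6.66, Arhgap15 5.02 and Casc4 -4.48 at 6 weeks. Between ages they were Cp 5.57, Myo6 -4.77, Axl 4.89, Apoe 8.60 and Cd83 3.60 in the constitutive and Itgam 2.36, Klk8 -2.67, Cd300c2 2.08, Adgrg1 2.51 and Tpm2 -3.22 in the inducible model.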

How the results depend on the processing

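The fits without inducible P0 control 56 and knockout 57 were chosen only after the result was seen. Of 285 counts of calls under alternatives 230 stayed within 1.5 times, and RLE size factors and limma-voom moved none. Of 9604 values of named genes 9041 kept direction and side of the threshold. Of the 122 list calls 81 held in the fry rotation test, among them 1 of 14 at E16, 5 of 15 at inducible P0 and none of the 8 and 7 at inducible 2 and 6 weeks, and 1 held with an estimated correlation. The calls at E16 (0) became 881 with DESeq2, 1576 with all 50 libraries and 3 with a sex term, those at inducible P0 (1823) 2911, 2743 and 705, and 1149 without control 56 and knockout 57. At inducible 2 weeks 313 became 662 with DESeq2, 888 without a filter, 84 with all 50 libraries and 19 with sex, and at 6 weeks 9 became 44, 25 and 14 with DESeq2, no filter and all 50 libraries. The model interaction at P0 (5946) became 3770 with all 50 libraries and the inducible age interaction (474) 1136 with DESeq2. Shared calls at P0 (672) became 1113 with all 50 libraries and 339 with sex, at 2 weeks (168) 350 with DESeq2, 467 without a filter, 67 with all 50 libraries and 7 with sex, and at 6 weeks (6) 19 with DESeq2 and 13 without a filter. With each replicate left out in turn, calls ran from 1153 to 1825 (constitutive 6 weeks), 0 to 638 (E16), 680 to 1638 (inducible P0), 94 to 938 (inducible 2 weeks), 5 to 18 (inducible 6 weeks), 3842 to 6067 (model interaction P0) and 254 to 645 (age interaction, inducible), and shared calls from 390 to 714 at P0, 58 to 543 at 2 weeks and 3 to 9 at 6 weeks. Directions turned for Hdac1 in constitutive P0 knockouts with limma-voom (-0.081) and without the library labelled knockout 68 (-0.74, highest 0.54 without knockout 76). They turned for Hdac1 at 6 weeks without the library labelled knockout 380 (-0.75, highest 1.69 without knockout No_379), and for Hdac2 at constitutive 2 weeks without knockout 80 (0.16, lowest -0.81 without knockout 89). For the type I interferon genes, the list interferon in knockout effect inducible 6wk turned upward without knockout 12 (adjusted p = 0.729) and had 7.49e-06 without knockout 9. For these moved or turned values the cause was not tested. A sex term could not be fitted at constitutive 6 weeks, where all libraries are female, nor for the shared calls there. No paired analysis was possible because the animal numbers name different animals and the labels give no litters. Depth limits genes with few counts, and scatter between replicates limits small changes, since on simulated data 11% of 2-fold changes were recovered at E16 (biological coefficient of variation 0.447) and 59% at constitutive P0 (0.253), both with 4 and 3 libraries.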

Other observations

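The tests in this part were chosen before their values were known, after the directions of the gene lists had been seen. A few genes changed alike in most of the 7 knockout comparisons. Trerf1 rose in 6 and Cx3cr1 fell in 6. Those that rose in 5 were Vim, Kcnab2, Bend4, Kbtbd11, Kank2, Scn3b, Ifi27, Trps1 and Maoa, of which Vim encodes vimentin and Maoa a monoamine oxidase, and those that fell in 5 included Il1rl1, Nrp2, Gpr155, Zcwpw1, Gp9, Siglecf, Lrrc75a, Itgb3, Myadml2, Liph, P3h2 and Slc12a2, among them an integrin (Itgb3) and an interleukin receptor gene (Il1rl1). Trps1, with log2 changes of 4.89 ± 0.19 in constitutive and 2.05 ± 0.29 in inducible knockouts at 6 weeks, and Trerf1, with 3.16 ± 0.31 and 1.90 ± 0.28, stayed up in young adults of both models.

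A hypothesis was that knockout microglia hold a younger expression pattern. Among genes called both in a knockout comparison and in the maturation of the controls of the other model, 83.2% (expected 51.4%) went against the change with age in constitutive knockouts at P0, 92.7% (expected 51.4%) at 2 weeks and 86.4% (expected 50.5%) at 6 weeks, and 84.4% (expected 52.3%) in inducible knockouts at P0 and 80.97% (expected 50.1%) at 2 weeks. Apoe, Mki67 and Mrc1, which fall with age in controls, rose in constitutive knockouts at 2 weeks, and Tmem119 and Selplg, which rise with age, fell. At P0 Apoe (-2.53 ± 0.19) and Igf1 (-2.21 ± 0.17), which fall with age, fell in constitutive knockouts, against this pattern. The shares match a younger pattern, but a gain of other cell types, whose markers are also higher in P0 controls, could give the same direction and stays open.

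Whether chance could give as many calls was weighed by regrouping the libraries. In the constitutive P0 comparison the real grouping called 7668 genes and the highest of the other 34 regroupings 4816, with control 70 grouped with the 3 knockouts, which points to a structure of the samples. Chance can be excluded to 1 in 35 there, at constitutive 6 weeks (1731 against at most 2), inducible P0 (1823 against 12), inducible 2 weeks (313 against 135), inducible 6 weeks (9 against 5) and in both maturation comparisons (10558 and 8793 against 0). The 135 at 2 weeks grouped the 3 male knockouts with control 4. A sex term left 19 calls, so genotype and sex stay mixed. At E16, with 0 calls in all 35, and for the 9 at 6 weeks beyond Hdac2, Cx3cr1 and Esr1, this test says nothing. For shared calls (672 against 6 at P0, 6 against 0 at 6 weeks) it says nothing, since most regroupings gave no calls to share. Regrouping also scrambles the knockout effects, so it cannot test interactions. Real and highest other counts were 5946 and 1983 (models, P0) and 767 and 1072 (6 weeks). For ages they were 3775 and 4379 (constitutive) and 474 and 1489 (inducible). As many or more came in 1, 3, 2 and 4 of 100 regroupings including the real one. Groups of 2 at constitutive 2 weeks allowed no such test.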
